A study of Mus musculus with 24 samples.

How the data were processed

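RNA was measured on Affymetrix mouse arrays, 1 array per sample, 24 samples in 8 groups of 3. Per the labels' protocols, cells were infected with lentivirus in medium with 8 µg/ml polybrene and given fresh medium after 24 hours. Harvest of the P19 cells followed at 72 hours. MEFs with MyoD were moved to differentiation medium at 48 hours and harvested 36 to 40 hours later, and a harvest time for MEFs labelled NeuroD2 is not given in the sources used here. Controls were untransduced. Biotin-labelled cRNA was made with the Affymetrix One-Cycle assay, per the labels' protocols. Groups, batches and replicate numbers were read from the sample titles and source names, because the characteristics of samples with MyoD describe neuronally differentiated cells.

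The values are log2 signal intensities as deposited by the authors, normalized between arrays before deposit, per the column quartiles of 23 arrays of the deposited table. The quartiles of P19 control replicate 2 of batch 1 (4.79 and 7.63) do not match, so whether that array was normalized with the others is not known. The background, normalization and summary methods are not given in the sources used here, and limma is the only tool that the submitters' processing notes name, without a version. The table has no detection calls. The values were used without further scaling. Column medians lay between 5.76 and 5.99, and the lowest and highest value of each array near 3 and 15, so low signals are compressed toward background and differences of weakly expressed genes can be understated.

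Of 45101 probe sets, 64 Affymetrix controls, 9160 without a gene symbol and 932 with several symbols were set aside. The remaining 34945 were reduced to 18193 genes by keeping, for each symbol, the probe set with the highest mean over all arrays; 9010 genes had more than 1. The called genes that the text names were checked in each main comparison, and a gene called in several was counted in each. Counted in this way, 89 cases had 162 other probe sets, of which 0 were called the other way and 56 were not called.

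A mean per group was fitted to each gene over all 24 arrays with limma 3.58.1 in R 4.3.3 (16 residual degrees of freedom, 3.89 prior degrees of freedom from empirical Bayes). Each factor was compared with the untransduced controls of its own batch. MEF and P19 controls were compared within batch 1, and the controls of each cell type between batches. Differences between effects were tested as contrasts of contrasts. All limma tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 18193 genes of each comparison. A gene passed at an adjusted p under 0.05. "Rose", "fell" and "called" refer to that threshold. Overlaps of genes at least 2-fold changed in both comparisons were tested with Fisher's exact test, two-sided, with all 18193 genes as background.

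Gene lists covered lineage bHLH factors and partners, myogenic regulators, sarcomere, muscle excitation, calcium and metabolism, and the neuromuscular junction. Neuronal lists covered transcription factors, cytoskeleton and RNA-binding genes, synaptic vesicle and release genes, and receptors, channels and adhesion genes. Others were the Notch pathway, bHLH inhibitors, pluripotency, neural progenitor, glia, early mesoderm and endoderm, cardiac, fibroblast and extracellular matrix, smooth muscle and myofibroblast, adipocyte, cartilage and bone, endothelial, epithelial, and blood and macrophage genes. The rest were S phase, G2 and M phase, cell cycle exit and p53 targets, interferon response, immediate early genes, unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, and oxidative phosphorylation. Of 815 entries, which include a list of the transduced factors, 762 were measured. The 32 lists were tested against the other genes with limma camera at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists. Each test was repeated with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move one way and does not compare them with other genes.

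The lists, comparisons, tests, alternatives and the rule for naming genes were chosen before the data were examined. The rule named Myod1 and Neurod2, then in each main comparison the 6 largest rises and 6 largest falls among called genes. These had to have groups that did not overlap and a higher group mean above 7.03, the median of all gene-level values, and clone or predicted-gene symbols were left out. It also named up to 4 called members of each list that camera called, and a fixed set of lineage, Notch, inhibitor and cell cycle genes whatever their values. For the other comparisons and for shared genes it named the 5 largest each way.

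The alternatives were quantile normalization again, a shift of each array to the same median, leaving out dim genes, the mean of all probe sets per gene, leaving out probe sets that can match several transcripts, and fitting only the arrays compared. Further ones were a trended robust prior, a replicate block, the controls of the other batch, leaving out each array in turn, an adjusted p under 0.01, a 2-fold minimum, overlaps without a fold minimum, and the estimated correlation and fry for lists. Leaving P19 control replicate 2 of batch 1 out of every fit was chosen after seeing the data.

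The procedure was tested on simulated data with known changes added to 67, 67 and 66 genes at 1.5-fold, 2-fold and 4-fold. Each gene had 1 spread, pooled over all groups, and P19 control replicate 2 of batch 1 was given a wider one. Other differences in spread between groups were not simulated. For MyoD in P19 cells it recovered 59.7%, 79.1% and 95.5% of them, with 17 false calls (9.83% of its calls, above the 5% of the threshold). For MyoD in MEFs it recovered 38.8%, 82.1% and 97%, for NeuroD2 in P19 cells 49.3%, 82.1% and 100%, and for MEFs labelled NeuroD2 40.3%, 83.6% and 98.5%. These had 1, 2 and 1 false calls. For MEF against P19 controls it recovered 52.2%, 77.6% and 93.9%, with 18 false calls (10.8%). For differences between effects the shares were 17.9%, 56.7% and 95.5% (MyoD, MEFs against P19 cells), 16.4%, 59.7% and 87.9% (NeuroD2, MEFs against P19 cells), 19.4%, 62.7% and 93.9% (factors in P19 cells), and 16.4%, 53.7% and 92.4% (factors in MEFs), with 2, 0, 3 and 0 false calls. Of the 32 lists, 0 without added change were called in any of these comparisons, and a list shifted on purpose was called in each. The simulated genes varied independently of each other. This check therefore cannot show false calls of lists whose genes vary together. The comparisons of controls between batches were not simulated. The number of arrays limits the precision.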

Results

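Gene expression was measured on 24 mouse microarrays in 8 groups of 3. P19 cells, a pluripotent mouse embryonal carcinoma line, and fibroblasts from mouse embryos lacking Myod1 and Myf5 (MEFs) were compared with and without a lentivirus carrying MyoD or NeuroD2. MyoD is the basic helix-loop-helix factor that starts the skeletal muscle programme, and NeuroD2 is a related factor of neurons. Batch 1 held untransduced and MyoD groups of both cells, batch 2 held untransduced MEFs and MEFs labelled NeuroD2, and batch 3 held untransduced P19 cells and P19 cells with NeuroD2. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between samples, which may be technical.

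In 23 of the 24 arrays the lower quartile lay between 4.47 and 4.58 and the upper between 8.23 and 8.40 on the log2 scale. P19 control replicate 2 of batch 1 stood apart, with quartiles of 4.79 and 7.63 and a spike-in (BioB) signal of 6.40 against 7.67 to 8.20 in the others. Its mean correlation across genes with the other arrays of its group was 0.917. The other arrays of that group had 0.958 and 0.956, and the remaining 21 had at least 0.986. It was kept, and the counts of genes called in each comparison are also given without it. Counts within lists and some overlaps are given with all arrays unless stated. That array widens the spread shared by all groups, so the counts of most other comparisons rose when it was left out.

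**Figure D1:**
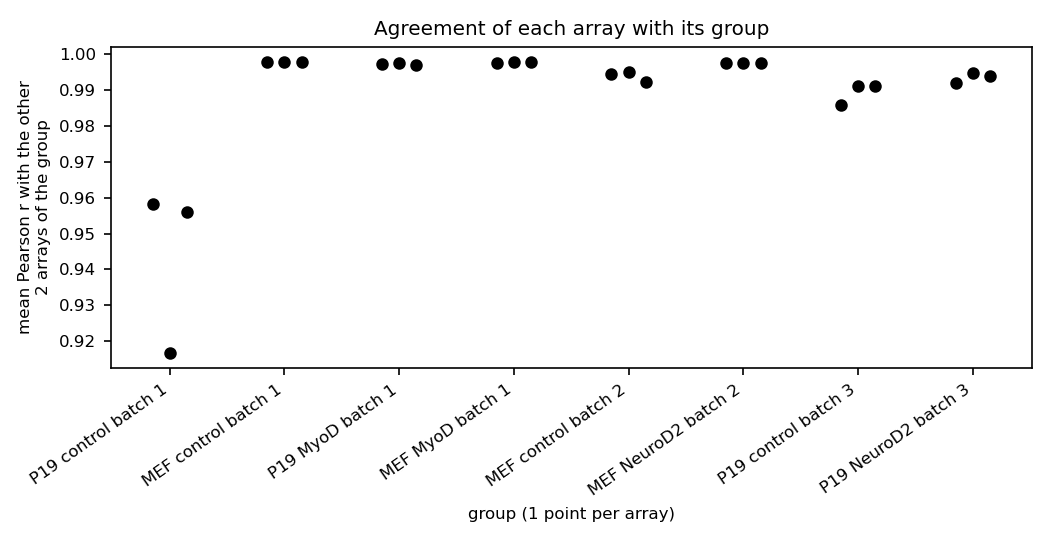
Mean Pearson correlation across genes of each array with the other arrays of its group (vertical axis), for the 8 groups (horizontal axis), with 1 point per array. P19 control replicate 2 of batch 1 lies lowest, at 0.917.

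The transduced genes were read first. Myod1 averaged 9.66 ± 0.082 (log2, SD, n = 3) in P19 cells with MyoD and 5.72 ± 0.288 in their controls. In MEFs it averaged 12.73 ± 0.107 with MyoD and 7.18 ± 0.035 without. These rises, 3.94 and 5.55 on the log2 scale, had limma adjusted p = 1.72e-14 and 1.86e-18. A second Myod1 probe set differed by 0.10 and 0.06 (adjusted p = 0.567 and 0.867). Neurod2 rose on 1 of its 3 probe sets in P19 cells with NeuroD2, from 5.98 ± 0.13 to 7.68 ± 0.423 (adjusted p = 1.85e-06). In the MEFs labelled NeuroD2 its 3 probe sets differed from control by -0.06, 0.21 and -0.12 (adjusted p = 0.943, 0.679 and 0.791), so no rise of Neurod2 RNA passed the test there. Myf5, 1 of the genes disrupted in these MEFs, read 10.07 in batch 1 controls; its probe set may lie outside the disrupted part, so this reading checks nothing.

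**Figure D2:**
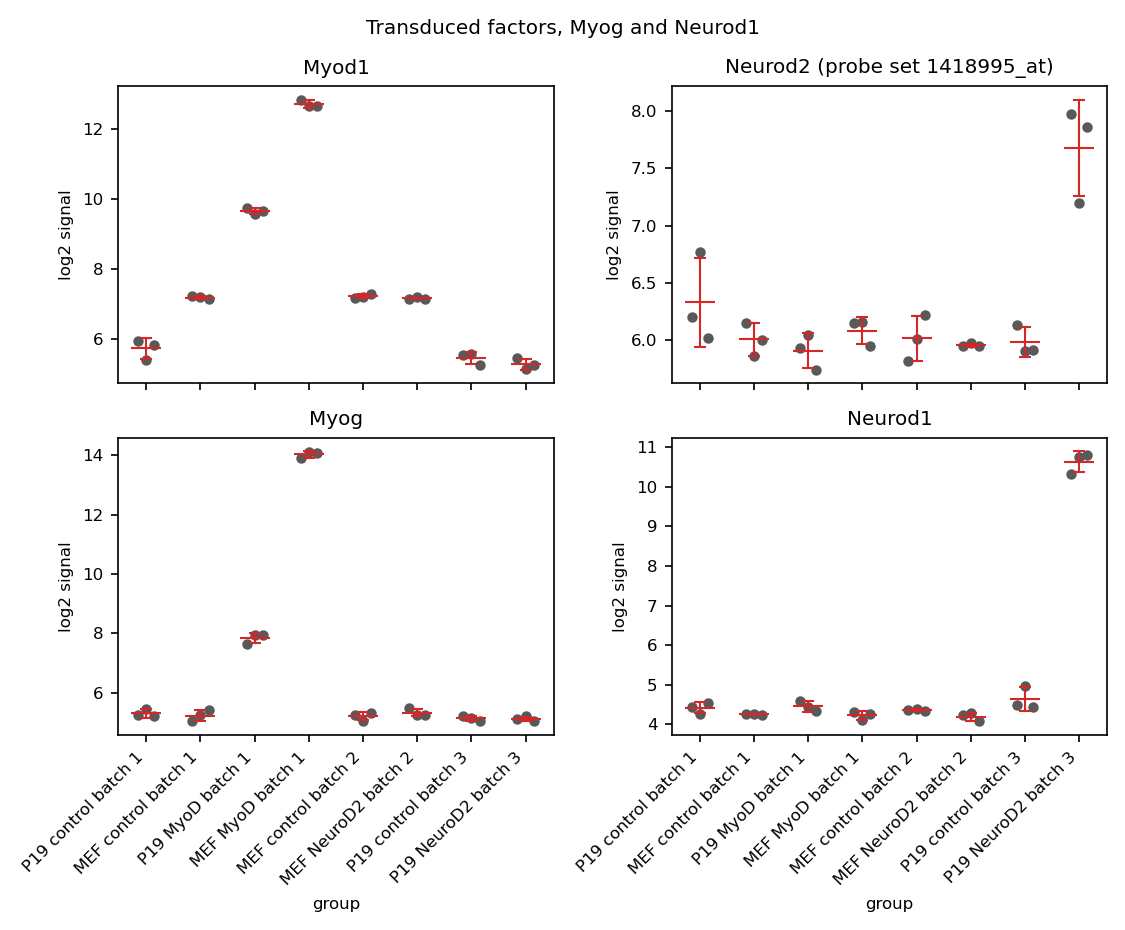
Log2 signal of the transduced factors, Myog and Neurod1 on every array, by group. Myog, a muscle factor downstream of MyoD, averaged 14.03 in MEFs with MyoD and 7.85 in P19 cells with MyoD.

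The starting state of the cells was compared in batch 1. Pou5f1, Lin28a and Sox2, genes of pluripotent cells, were lower in MEFs by -8.82, -8.45 and -7.75 on the log2 scale (limma adjusted p = 5.77e-20, 1.03e-19 and 5.86e-15). Aspn and Bgn, small proteoglycans of connective tissue, were higher by 8.99 and 8.72 (adjusted p = 2.91e-21 and 9.77e-17). Slc2a3, a glucose transporter, and Igfbp2 were lower by -8.58 and -7.76, while Cavin2, S100a4 and Osmr were higher by 8.19, 7.99 and 7.97. Of 39 fibroblast and extracellular matrix genes, 37 were higher in MEFs and 0 lower (median 4.81, camera adjusted p = 0.00145 with an estimated correlation). Of 32 pluripotency genes, 28 were lower and 2 higher (median -4.07, adjusted p = 0.00958 with an estimated correlation). Of 27 interferon response genes, 24 were higher (median 3.41, adjusted p = 0.00145 with an estimated correlation). All 30 genes of G2 and M phase were lower (median -2.89), with a camera adjusted p = 0.252 with an estimated correlation. Limma called 4511 genes higher and 4887 lower of 18193, and 4381 and 5704 without the array that stood apart.

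The next comparison asked what MyoD did in P19 cells, which are not of the muscle lineage. Klhl41, a muscle protein of the sarcomere and reticulum, rose by 4.75 ± 0.12 (log2, SE, n = 3 per group), and Myog, the factor that drives muscle differentiation, by 2.54 ± 0.12 (limma adjusted p = 1.78e-16 and 1.25e-11). Myo5b, a myosin motor of membrane traffic, and Smarcd3, a chromatin remodelling subunit of heart and muscle, rose by 4.09 and 3.34. Of 22 myogenic regulators, 9 rose, 0 fell and 13 did not pass (12 higher adjusted over the list alone, median 0.61; camera adjusted p = 1.17e-08, and adjusted p = 0.00706 with an estimated correlation). They included Rbm24, an RNA-binding splicing factor, at 1.96 and Eya1, a transcriptional coactivator, at 2.01. Myf6, another muscle factor, differed by -0.03 (adjusted p = 0.844). Limma called 370 genes higher and 123 lower, and 381 and 337 without the array that stood apart, with 402 genes called in both fits. Quantile normalization again gave 417 higher and 348 lower.

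Muscle structural genes rose in part. Of 42 sarcomere genes, 16 rose, 1 fell and 25 did not pass (21 and 2 adjusted over the list alone, median 0.35; camera adjusted p = 4.53e-08, but adjusted p = 0.167 with an estimated correlation). Tnnc2, the calcium-binding subunit of fast troponin, rose by 2.96, Tnnt2, a troponin T of heart and embryonic muscle, by 2.59, and Ttn, the giant elastic protein titin, by 2.63. Of 13 neuromuscular junction genes, 4 rose and 9 did not pass (4 adjusted over the list alone, median 0.26; camera adjusted p = 0.00303, but adjusted p = 0.167 with an estimated correlation). They were Chrna1 at 2.80 and Chrnb1 at 1.60, subunits of the muscle acetylcholine receptor, Rapsn, which clusters that receptor, at 2.69, and Musk, its receptor kinase partner. That camera call ended without P19 control replicate 1 (adjusted p = 0.0662) or replicate 3 (0.123) of batch 1. Of 34 genes of muscle excitation, calcium and metabolism, 5 rose and 29 did not pass (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0632), and 10 rose without the array that stood apart. Without the array that stood apart, the sarcomere, junction and excitation lists had adjusted p = 0.00178, 0.000329 and 0.00185 with an estimated correlation.

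Krt19, a keratin of simple epithelia, fell by 1.80 in P19 cells with MyoD, Lgals3, a galectin, fell by 1.93, and Bmp4, a growth factor of early patterning, fell by 1.5 (limma adjusted p = 0.000643, 1.73e-05 and 0.00242). Of 24 early mesoderm and endoderm genes, 5 fell and 1 rose (12 and 2 adjusted over the list alone, median -0.43; camera adjusted p = 3.04e-05, and adjusted p = 0.0374 with an estimated correlation). Without the array that stood apart 2 fell and 1 rose (adjusted p = 0.0135 with an estimated correlation). Eomes, a T-box factor, was lower by -1.23 and Gsc, a homeobox factor, by -1.60; the chemokine receptor Cxcr4 was higher by 1.74. Pou5f1 and Nanog, factors of pluripotency, differed by 0.02 and -0.12, and Neurod1, a neuronal factor, by 0.04 (adjusted p = 0.92, 0.82 and 0.854). None of 32 pluripotency genes passed (camera adjusted p = 0.0558); without the array that stood apart, 4 fell (adjusted p = 0.00694 with an estimated correlation). Against the P19 controls of batch 3, Nanog was lower (-1.25, adjusted p = 0.032), and the calls of Bmp4 (0.24) and Cxcr4 (0.481) ended.

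Several other lists passed with the preset correlation in P19 cells with MyoD and lost their call with an estimated one. The fibroblast and extracellular matrix list had 1 lower gene of 39 (Col1a1, a fibrillar collagen; 7 lower and 1 higher adjusted over the list alone, median -0.34; camera adjusted p = 2.54e-05, but adjusted p = 0.167 with an estimated correlation). Without the array that stood apart, 7 of its genes were lower (16 adjusted over the list alone; adjusted p = 0.0563 with an estimated correlation). The epithelial list (2 lower of 14, Krt19 and Cldn7), the endothelial list (1 lower of 12, Flt1) and the glia list (1 higher of 18, Mbp, against a median of -0.18) had adjusted p = 0.167 with an estimated correlation. The synaptic vesicle list (1 lower of 37, Syt11) and the blood and macrophage list (0 of 12) had adjusted p = 0.441 and adjusted p = 0.366 with an estimated correlation. S phase (0 of 29), G2 and M phase (0 of 30) and oxidative phosphorylation (0 of 27) had positive medians of 0.28, 0.27 and 0.23, and adjusted p = 0.586, adjusted p = 0.628 and adjusted p = 0.537 with an estimated correlation. Without the array that stood apart (P19 control replicate 2 of batch 1), the endothelial, glia, synaptic, blood, S phase and oxidative phosphorylation calls ended (camera adjusted p = 0.17, 0.37, 0.56, 0.548, 0.178 and 0.0926), and the G2 and M phase median was -0.001 (0.835). The glia and synaptic calls also ended without replicate 1 of those controls (0.0634 for each), and the glia call without P19 MyoD replicate 1 (0.067). Of the 7 other probe sets of Mbp, 1 was called higher (0.64, limma adjusted p = 0.00689) and 6 were not called (-0.67 to 0.29). The Mbp call ended with the mean of all probe sets (0.125, adjusted p = 0.416) and with quantile normalization again (0.148). The lists of Notch pathway (5 higher of 25), bHLH inhibitors (5 of 15), lineage bHLH factors (3 of 15), cardiac genes (4 of 20) and smooth muscle (3 of 16) had camera adjusted p = 0.0558, 0.262, 0.0558, 0.495 and 0.886. The lineage bHLH list includes Myod1, the transduced gene, which is among its higher genes. Without the array, that list was called (5.06e-05, and adjusted p = 0.00185 with an estimated correlation). So were the Notch (0.00226), bHLH inhibitor (0.0362), cardiac (0.0245), neural progenitor (0.0362), immediate early (0.000723) and glycolysis and hypoxia lists (0.000556), which had adjusted p = 0.0756, 0.0707, 0.312, 0.175, 0.0563 and 0.151 with an estimated correlation.

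The size of the MyoD effect in P19 cells rested on its controls. The higher and lower counts were 3758 and 2358 without P19 control replicate 1 of batch 1, 4837 and 3027 without replicate 3, and 202 and 48, 212 and 57, and 203 and 36 without P19 MyoD replicate 1, 2 or 3 in turn. Without control 1 or 3, the array that stood apart is 1 of only 2 controls. With only the 6 arrays compared in the fit, 45 genes were higher and 5 lower. The calls of Klhl41, Myo5b, Smarcd3, Myog, Tnnc2, Tnnt2, Chrna1, Rapsn, Krt19 and Bmp4 held in that fit, while those of Lgals3, Ttn, Musk, Chrnb1, Rbm24, Eya1, Eomes, Gsc, Cxcr4, Col1a1, Cldn7, Flt1, Syt11 and Mbp ended. Against the P19 controls of batch 3, 934 were higher and 1142 lower, so the balance of rises and falls turned, and the calls of Syt11, Col1a1 and Cldn7 ended (adjusted p = 0.215, 0.0726 and 0.0707). Leaving out 1 of the MyoD replicates ended the calls of Gsc, Eomes, Col1a1, Mbp, Cxcr4 and Syt11, and without the array that stood apart Gsc, Col1a1 and Syt11 had adjusted p = 0.0719, 0.0546 and 0.0538.

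In MEFs, MyoD was followed by a far larger set of changes. Tnnc2 rose by 9.05 ± 0.18 (log2, SE, n = 3 per group), Myh3, the embryonic myosin heavy chain, by 8.80 ± 0.16, and Myog by 8.79 ± 0.12, from 5.24 to 14.03 (limma adjusted p = 2.92e-19, 6.67e-20 and 1.06e-21). Actc1, an actin of heart and embryonic muscle, Tnni1, slow troponin I, and Mylpf, a fast myosin light chain, rose by 8.90, 8.76 and 8.71. Of 42 sarcomere genes, 36 rose, 0 fell and 6 did not pass (36 adjusted over the list alone, median 5.25; camera adjusted p = 3.76e-52, and adjusted p = 0.000178 with an estimated correlation). Of 22 myogenic regulators, 16 rose and 3 fell (17 and 3 adjusted over the list alone, median 2.44; adjusted p = 8.7e-05 with an estimated correlation). Mymk and Mymx, the membrane proteins that fuse myoblasts, rose by 8.35 and 7.76, and Mef2c, a partner of MyoD, by 4.28; Myf6 differed by 0.14 (adjusted p = 0.532). Limma called 1963 genes higher and 2638 lower, and 3302 and 4087 without the array that stood apart, which included all 4601 of the first fit.

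The machinery of muscle function rose as well. Of 34 genes of muscle excitation, calcium and metabolism, 30 rose and 4 did not pass (30 adjusted over the list alone, median 3.23; camera adjusted p = 2.36e-05 with an estimated correlation). Ryr1, the calcium release channel, rose by 6.23, Atp2a1, the calcium pump that refills its store, by 5.73, and Srl, sarcalumenin of that store, by 7.02. Of 13 neuromuscular junction genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 2.65; adjusted p = 0.00177 with an estimated correlation), with Chrng, the fetal receptor subunit, at 6.53 and Rapsn at 4.73. Cdkn1c and Cdkn1a, inhibitors of the cell cycle, rose by 4.58 and 1.84 (limma adjusted p = 9.29e-16 and 2.14e-09). Of 27 oxidative phosphorylation genes, 22 rose and 5 did not pass (23 adjusted over the list alone, median 0.57; camera adjusted p = 5.67e-11, but adjusted p = 0.377 with an estimated correlation, and 0.00313 without the array that stood apart). Cyc1 and Cycs, cytochromes of the respiratory chain, rose by 1.20 and 1.00.

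Matrix and interferon genes fell in MEFs with MyoD. Of 39 fibroblast and extracellular matrix genes, 28 fell, 1 rose and 10 did not pass (29 and 1 adjusted over the list alone, median -1.34; camera adjusted p = 2.51e-15, and adjusted p = 0.00738 with an estimated correlation). Pdgfra, a growth factor receptor of mesenchymal cells, fell by 4.47, Fbln1, an elastic fibre protein, fell by 2.97, and Mmp2, a matrix protease, fell by 2.86. Of 27 interferon response genes, 22 fell and 5 did not pass (24 adjusted over the list alone, median -1.93; camera adjusted p = 8.62e-23, and adjusted p = 0.000135 with an estimated correlation). Oasl2, Gbp2 and Ifit3, proteins of antiviral defence, fell (-4.73, -4.46 and -4.09). Lcn2, an iron-binding protein of inflammation, Cxcl5, a neutrophil chemokine, and Mmp3, a matrix protease, fell (-5.72, -5.62 and -4.56). Col11a1, a fibrillar collagen of cartilage, and Tgfbi, a secreted adhesion protein, fell (-4.74 and -4.52). The controls were untransduced and not stated to be in differentiation medium, so virus, medium and MyoD are not separated in these MEFs.

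Other lists in MEFs with MyoD passed camera with the preset correlation and not with an estimated one. Of 30 genes of G2 and M phase, 12 rose and 0 fell (15 adjusted over the list alone, median 0.50; camera adjusted p = 4e-05, but adjusted p = 0.685 with an estimated correlation), with Cenpf, a kinetochore protein, at 1.03 and Mki67, the proliferation antigen, at 0.77. Of 29 S phase genes, 7 rose (8 adjusted over the list alone, median 0.28; adjusted p = 0.828 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at 2.20. Of 18 cholesterol synthesis genes, 12 fell and 2 rose (14 and 2 adjusted over the list alone, median -0.75; adjusted p = 0.455 with an estimated correlation), with Sqle, squalene epoxidase, at -1.11. Of 16 smooth muscle and myofibroblast genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.59; adjusted p = 0.362 with an estimated correlation), with the filament protein Des at 4.90. Of 25 Notch pathway genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.20; adjusted p = 0.272 with an estimated correlation). The ligand Dll1 rose by 4.27 and the receptor Notch1 by 3.02, and Mfap4, a microfibril protein of the list, fell by 2.82. Of 20 cardiac genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.07; adjusted p = 0.614 with an estimated correlation), and the risen Tnnt2 (8.65), Myl4 (7.89) and Myh7 (4.97), contractile proteins, also belong to the sarcomere list. The cardiac call ended without the array that stood apart (camera adjusted p = 0.0591), and the Notch call against the MEF controls of batch 2 (0.114).

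**Figure D3:**
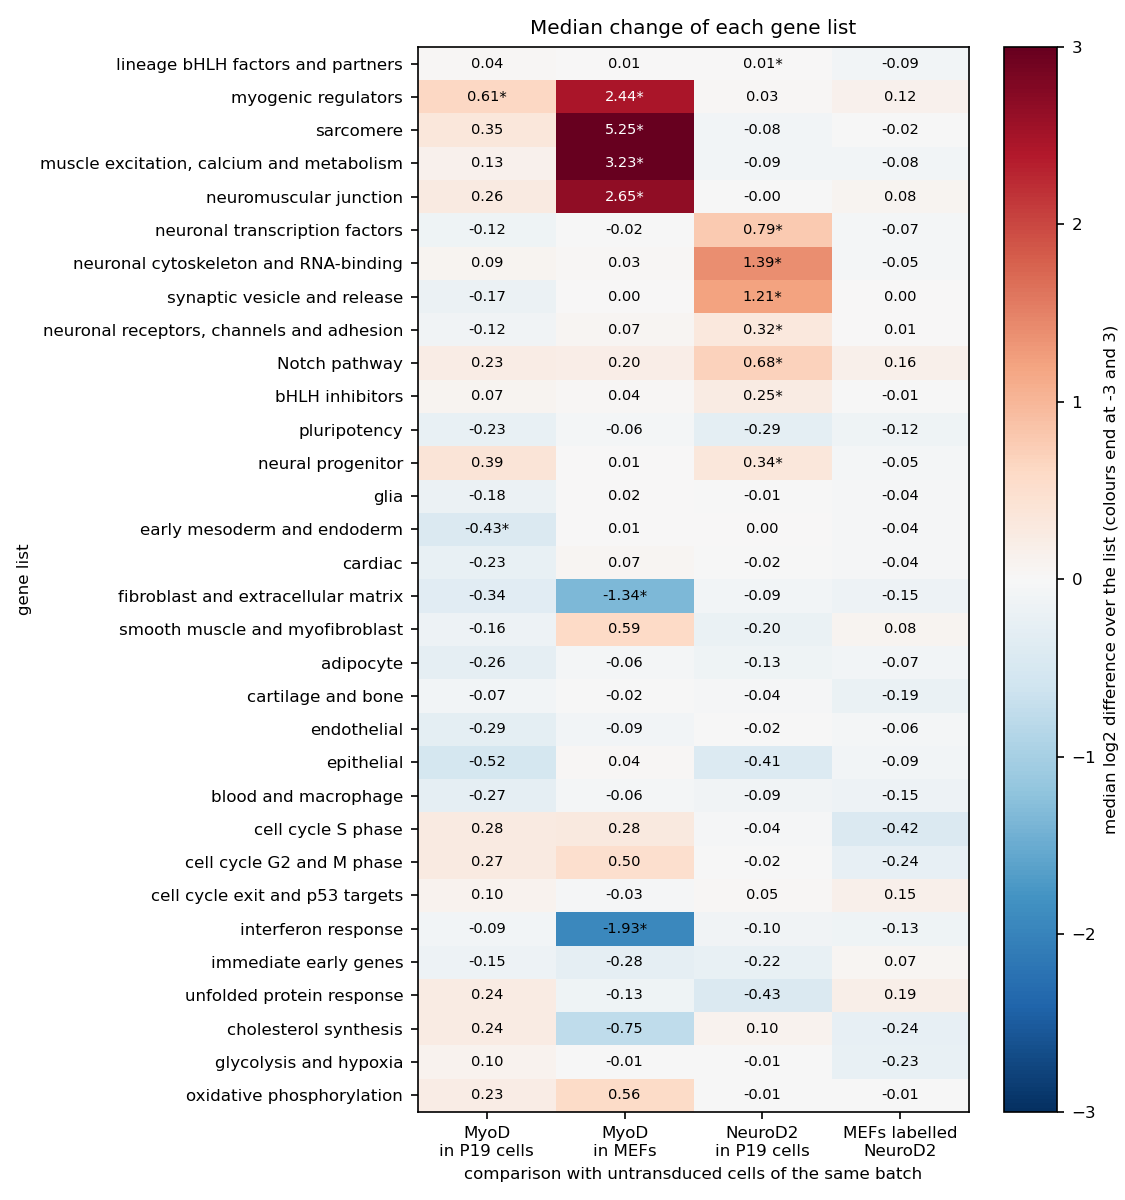
Median log2 difference of each gene list (vertical axis) in the 4 main comparisons (horizontal axis), printed in each cell. Colours end at -3 and 3, and an asterisk marks a camera adjusted p under 0.05 with an estimated correlation.

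The MyoD effects in MEFs and P19 cells were then compared directly. The rise of Tnnt3, a fast troponin T, was larger in MEFs by 8.31 (8.32 in MEFs and 0.01 in P19 cells), and that of Mymk by 8.00 (8.35 and 0.34; limma adjusted p = 3.3e-16 and 1.61e-15). Over the 42 sarcomere genes, 35 rose more in MEFs and 0 less (median 4.62, camera adjusted p = 0.000277 with an estimated correlation). The interferon list fell more in MEFs for 22 of 27 genes (median -1.79, adjusted p = 0.000277 with an estimated correlation). Most genes of this list were already lower in P19 than in MEF controls, so a fall in P19 cells may be understated near background. Limma called 3840 genes with different effects (1163 higher and 2677 lower in MEFs), 5559 without the array that stood apart (2495 and 3064) and 6069 without P19 control replicate 3 of batch 1. At least 2-fold in both cells, 84 genes rose where 8.19 were expected (Fisher's exact p = 3.62e-64, odds ratio 20.2), among them Klhl41 (4.75 in P19 cells and 6.13 in MEFs) and Synpo2l, a Z-disc protein (3.79 and 7.81). The overlap was 61 without the array that stood apart, 134 without P19 control replicate 1 and 147 without replicate 3 of batch 1. At the same fold, 5 genes fell in both, where 1.6 were expected (Fisher's exact p = 0.0199), including Anxa2, a membrane-binding protein, at -1.09 and -1.35. Synpo2l in P19 cells was -0.27 when probe sets that can match several transcripts were left out. Another Synpo2l probe set, also outside that class, rose there by 3.54 (limma adjusted p = 3.47e-09). The call of Synpo2l ended with only the 6 arrays compared (adjusted p = 0.0975).

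**Figure D4:**
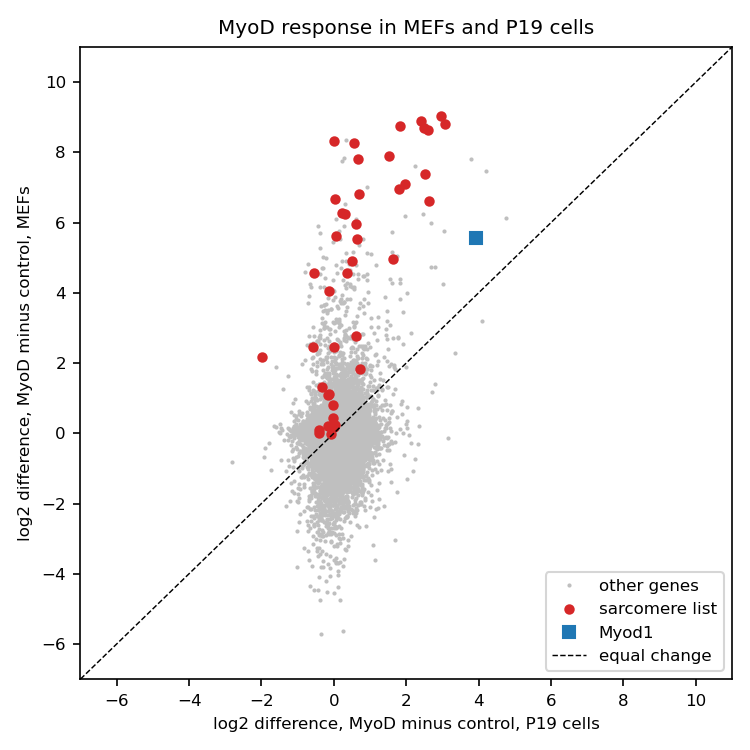
Log2 difference of each gene with MyoD in P19 cells (horizontal axis) and in MEFs (vertical axis), with 1 point per gene. Across genes Pearson's r was 0.157 and Spearman's rho 0.024, and 0.300 and 0.135 without P19 control replicate 2 of batch 1; genes are not independent replicates.

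Neuronal genes rose in P19 cells with NeuroD2. Chgb, a granin of secretory granules, rose by 6.81 ± 0.21 (log2, SE, n = 3 per group), from 4.67 to 11.48, Nhlh2, a neuronal bHLH factor, by 6.29 ± 0.19, and Neurod1 by 6.0 ± 0.14 (limma adjusted p = 3.28e-15, 1.78e-15 and 7.83e-17). Onecut2 and Ebf2, transcription factors of developing neurons, and Uncx, a homeobox factor, rose by 5.37, 5.31 and 5.04. Of 35 neuronal transcription factors, 16 rose and 19 did not pass (18 adjusted over the list alone, median 0.79; camera adjusted p = 4.15e-30, and adjusted p = 7e-06 with an estimated correlation). Of 34 genes of the neuronal cytoskeleton and RNA binding, 28 rose (31 adjusted over the list alone, median 1.39; adjusted p = 0.000813 with an estimated correlation), with Dcx, the microtubule protein doublecortin, at 4.25 and Map2, a dendritic microtubule protein, at 4.18. Of 37 synaptic vesicle genes, 25 rose (25 adjusted over the list alone, median 1.21; adjusted p = 1.82e-05 with an estimated correlation), with Syp, synaptophysin, at 3.64. Of 42 neuronal receptors, channels and adhesion genes, 16 rose (18 adjusted over the list alone, median 0.32; adjusted p = 0.000813 with an estimated correlation), with Chrnb4, a neuronal acetylcholine receptor subunit, at 3.07. Limma called 928 genes higher and 589 lower, and 1992 and 2034 without the array that stood apart, which included all 1517 of the first fit. The lower count was 330 without P19 NeuroD2 replicate 2, and against the P19 controls of batch 1 the counts were 3046 and 2077.

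Notch, progenitor and inhibitor genes rose beside them. Of 25 Notch pathway genes, 12 rose and 13 did not pass (12 higher and 1 lower adjusted over the list alone, median 0.68; camera adjusted p = 8.22e-19, and adjusted p = 8.14e-05 with an estimated correlation). Dll3 and Dll1, Notch ligands, rose by 4.64 and 2.26, and Mfng, an enzyme that modifies Notch, by 3.10; Mfap4, a microfibril protein of the list, rose by 2.56. Of 15 bHLH inhibitors, 5 rose (6 and 1 lower adjusted over the list alone, median 0.25; adjusted p = 0.000457 with an estimated correlation), with Id1, which blocks bHLH dimers, at 1.94 and Hes5, a Notch target, at 1.47. Of 21 neural progenitor genes, 9 rose (9 adjusted over the list alone, median 0.34; adjusted p = 0.00192 with an estimated correlation), with Olig2 and Pax6, progenitor factors, at 3.47 and 3.25. Of 15 lineage bHLH factors, 2 rose (2 adjusted over the list alone, median 0.01; adjusted p = 0.00895 with an estimated correlation), and these were Neurod1 and Neurod4, at 6.0 and 3.25. The median of that list was -0.002 without P19 control replicate 2 of batch 3. Myog, Myf5 and Sox2 differed by -0.02, -0.02 and -0.15 (limma adjusted p = 0.984, 0.993 and 0.92).

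Some genes of pluripotent and epithelial cells fell with NeuroD2 in P19 cells. Dnmt3l, a DNA methylation cofactor, fell by 2.13, Esrp1, an epithelial splicing factor, fell by 2.16, Folr1, a folate receptor, fell by 2.04 and Dcn, a matrix proteoglycan, fell by 2.90 (limma adjusted p = 3.01e-07, 3.22e-05, 4.33e-05 and 1.04e-08). Of 32 pluripotency genes, 8 fell and 24 did not pass (8 adjusted over the list alone, median -0.29; camera adjusted p = 4.52e-05, but adjusted p = 0.121 with an estimated correlation), while Pou5f1 and Nanog differed by -0.37 and 0.20 (limma adjusted p = 0.209 and 0.917). Of 14 epithelial genes, 5 fell (5 adjusted over the list alone, median -0.41; camera adjusted p = 2.55e-05, but adjusted p = 0.0759 with an estimated correlation). Of 27 interferon genes, 4 fell (5 adjusted over the list alone, median -0.11; adjusted p = 0.381 with an estimated correlation), with Bst2, an antiviral membrane protein, at -1.34. The unfolded protein response list had 0 of 18 genes past the test and a median of -0.43 (camera adjusted p = 0.000213, but adjusted p = 0.624 with an estimated correlation), and its call ended without P19 NeuroD2 replicate 1 (adjusted p = 0.714). The interferon call ended without the array that stood apart (0.109). Against the P19 controls of batch 1, the calls of the pluripotency list (adjusted p = 0.33), the unfolded protein response list (0.33), the lineage bHLH list (0.179) and Dmrt1, a factor of germ cells (0.957), ended, and Nanog was higher (1.32, adjusted p = 0.0135).

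The MEFs labelled NeuroD2 were compared with batch 2 controls. Igfbp5, a binding protein of insulin-like growth factors, rose by 7.92 ± 0.375 (log2, SE, n = 3 per group), Dner, a transmembrane Notch ligand of neurons, by 7.29 ± 0.25, Mest, an imprinted gene, by 6.49 ± 0.19, and Tnr, a matrix protein of the nervous system, by 4.61 ± 0.14 (limma adjusted p = 2.31e-12, 9.91e-15, 5.76e-16 and 1.92e-15). Ackr3, an atypical chemokine receptor, rose by 4.98. Mmp3 fell by 8.09, and the chemokines Ccl11, Cxcl5 and Ccl8 fell (-7.37, -5.97 and -5.93). Neurod1 and Neurod4 differed by -0.17 and -0.10 (adjusted p = 0.621 and 0.905). Of 35 neuronal transcription factors, 1 rose (camera adjusted p = 0.78). Of 34 neuronal cytoskeleton genes, 6 rose and 5 fell, with a median of -0.05, a positive mean of 0.10 and adjusted p = 0.78. Limma called 1166 genes higher and 1080 lower, and 2506 and 2422 without the array that stood apart, which included all 2246 of the first fit.

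None of the 32 lists held with an estimated correlation in the MEFs labelled NeuroD2. Of 25 Notch pathway genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone, median 0.16; camera adjusted p = 6.08e-06, but adjusted p = 0.0739 with an estimated correlation), with Dner at 7.29, the ligand Jag1 at 4.21 and Dll1 at 2.25. Of 29 S phase genes, 11 fell (14 adjusted over the list alone, median -0.42; camera adjusted p = 8.94e-07, but adjusted p = 0.955 with an estimated correlation), with Cdt1 and Mcm6, which license replication origins, at -2.26 and -1.69. Of 30 genes of G2 and M phase, 6 fell (8 adjusted over the list alone, median -0.24; adjusted p = 0.955 with an estimated correlation), with Bub1b, a mitotic checkpoint kinase, at -0.75. Of 23 glycolysis and hypoxia genes, 8 fell and 3 rose (9 and 3 adjusted over the list alone, median -0.23; adjusted p = 0.955 with an estimated correlation), with Hk2, a hexokinase, at -1.36. Without MEF control replicate 1 of batch 2, the G2 and M phase list (adjusted p = 0.296) and the glycolysis list (0.0958) lost their calls, leaving 2 lists of 4; without MEF NeuroD2 replicate 3 the G2 and M phase list had adjusted p = 0.102.

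The differences from control in P19 cells with NeuroD2 and in MEFs labelled NeuroD2 were compared directly. Chgb, Nhlh2 and Neurod1 had lower effects in the MEFs labelled NeuroD2, with differences of -6.96, -6.39 and -6.18 (limma adjusted p = 7.49e-13, 4.61e-13 and 5.76e-15). Mest and Tnr had higher effects there, with differences of 6.18 and 4.49. Of the neuronal transcription factors, 15 of 35 had a lower effect in MEFs and 0 a higher one (median -0.96, camera adjusted p = 7.2e-05 with an estimated correlation). Of the neuronal cytoskeleton genes, 22 of 34 were lower and 2 higher (median -1.65, adjusted p = 0.0263 with an estimated correlation). Limma called 1849 genes with different effects (825 higher and 1024 lower), and 4520 without the array that stood apart (2285 and 2235). At least 2-fold in both cells, 68 genes rose where 12.24 were expected (Fisher's exact p = 1.94e-31, odds ratio 7.22), among them Dner (3.73 in P19 cells and 7.29 in MEFs) and Ppp1r14a, a phosphatase inhibitor (3.74 and 3.59). Another 7 genes fell in both where 2.69 were expected (Fisher's exact p = 0.0184), including F3, tissue factor, and Steap3, a ferrireductase, and 11 did without the array that stood apart (3.21 expected, p = 0.000381). Cell type and batch cannot be told apart here, since the MEFs labelled NeuroD2 and the P19 cells with NeuroD2 are from batches 2 and 3.

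The groups with MyoD and those labelled NeuroD2 were also compared within each cell type, across batches. Factor and batch are therefore not separated in these comparisons. In P19 cells Klhl41, Synpo2l and Tnnc2 had higher effects with MyoD, with differences of 4.95, 4.86 and 3.37. Chgb, Nhlh2 and Rgs4, a regulator of G-protein signalling, had lower effects, with differences of -6.77, -6.08 and -5.36 (limma adjusted p at most 0.00078 for all of these). Synpo2l was -0.19 when probe sets that can match several transcripts were left out, and had adjusted p = 0.0565 with only the arrays compared. Another Synpo2l probe set outside that class rose by 3.54 with MyoD in P19 cells (limma adjusted p = 3.47e-09). Of 34 neuronal cytoskeleton genes, 20 had a lower effect with MyoD (median -1.47, camera adjusted p = 0.00728 with an estimated correlation). Of 42 sarcomere genes, 15 had a higher and 1 a lower effect (median 0.43, adjusted p = 0.104 with an estimated correlation). Limma called 1006 genes (473 higher and 533 lower), 1996 without the array that stood apart (823 higher and 1173 lower), and 1806 and 2470 without P19 control replicate 1 or 3 of batch 1. At least 2-fold, 42 genes rose in P19 cells with MyoD and in those with NeuroD2, where 4.79 were expected (Fisher's exact p = 8.64e-28). They included Megf10, an engulfment receptor, and Cdk5r1, an activator of the neuronal kinase Cdk5. That overlap was 27 without the array that stood apart, and 73 and 78 without P19 control replicate 1 or 3 of batch 1. Another 2 genes fell in both, where 0.17 were expected (Fisher's exact p = 0.0121), 1 of them Lgals3 (-1.93 and -1.28), and 6 did without the array that stood apart (0.33 expected, p = 8.4e-07).

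In MEFs, Tnnc2, Tnni1 and Myog rose more with MyoD than in MEFs labelled NeuroD2 by 8.98, 8.96 and 8.68, while Serping1, an inhibitor of complement, Fat4, a cadherin, and Dner rose less or fell, with differences of -5.66, -5.62 and -5.31 (limma adjusted p at most 4.46e-07). Of 42 sarcomere genes, 34 had a higher effect with MyoD (median 5.14, camera adjusted p = 0.000179 with an estimated correlation). The matrix list had 25 lower effects of 39 (median -1.33, adjusted p = 0.0142 with an estimated correlation) and the interferon list 19 of 27 (median -1.96, adjusted p = 0.000179 with an estimated correlation). Limma called 3427 genes (1516 higher and 1911 lower), and 6498 without the array that stood apart (2961 and 3537). At least 2-fold, 115 genes rose in MEFs with MyoD and in MEFs labelled NeuroD2, where 20.94 were expected (Fisher's exact p = 1.63e-53, odds ratio 7.94), including Mest (5.54 with MyoD and 6.49 labelled NeuroD2) and Igf1, a growth factor (3.51 and 3.64). Another 220 fell in both, where 25.73 were expected (Fisher's exact p = 6.15e-156, odds ratio 20.3), including Cxcl5 (-5.62 and -5.97), Mmp3 (-4.56 and -8.09) and Agtr2, an angiotensin receptor (-4.06 and -4.44). All transduced cells and no controls received virus, so these overlaps do not part the factors from infection. The MEF groups also come from different batches, and only the MEFs with MyoD are stated to be in differentiation medium. Differences between them do not part the factors from medium and batch.

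Untransduced cells differed between batches. In P19 controls, Egln3 and Ankrd37, hypoxia-induced genes, and Slc16a3, a lactate transporter, were higher in batch 3 by 2.73, 2.56 and 2.68, and Peg10, an imprinted gene, by 4.12 (limma adjusted p = 2.58e-05, 4.45e-06, 1.87e-08 and 2.33e-08). Of 23 glycolysis and hypoxia genes, 18 were higher (median 1.03, camera adjusted p = 1.17e-15, but adjusted p = 0.517 with an estimated correlation). Limma called 2569 genes (1936 higher and 633 lower in batch 3), 3171 without the array that stood apart (1508 higher and 1663 lower, so the excess of higher genes ended), 6485 and 7607 without P19 control replicate 1 or 3 of batch 1, and 1668 and 1576 without replicate 1 or 3 of batch 3. In MEF controls, Bub1, a mitotic checkpoint kinase, and Mki67 were lower in batch 2 by -1.97 and -1.68, and Mmp3 was higher by 1.83. Of 30 genes of G2 and M phase, 28 were lower (median -1.23, adjusted p = 0.0272 with an estimated correlation). Limma called 415 MEF genes (211 higher and 204 lower), and 2970 without the array that stood apart (1228 and 1742). The count was 231, 215 and 186 without MEF control replicates 1, 2 and 3 of batch 1 in turn, and 270, 267 and 193 without those of batch 2. With only the 6 arrays compared, 1 P19 gene and 3154 MEF genes were called, and the calls of Peg10, Egln3 and Ankrd37 ended.

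Few genes of the adipocyte list and of the cartilage and bone list were called. The adipocyte list had 0 higher and 0 lower of 10 genes with MyoD in P19 cells and 1 and 2 in MEFs, and the cartilage and bone list 1 and 0 of 15 and 2 and 2. The adipocyte list had 0 and 1 in P19 cells with NeuroD2 and 2 and 0 in MEFs labelled NeuroD2, and the cartilage list 2 and 1 and then 1 and 3. Immediate early genes, 18 in number, had 1 higher and 6 lower with MyoD in MEFs (camera adjusted p = 0.16) and 7 and 3 in MEFs labelled NeuroD2 (0.341). Cell cycle exit and p53 targets, 23 in number, had 6 higher and 5 lower with MyoD in MEFs (0.747) and 3 and 1 with NeuroD2 in P19 cells (0.153). With the preset correlation 13, 13, 12 and 4 of the 32 lists passed in the 4 main comparisons (MyoD in P19 cells and MEFs, NeuroD2 in P19 cells, and MEFs labelled NeuroD2). With an estimated correlation 2, 6, 8 and 0 passed, and without the array that stood apart 7, 7, 9 and 0 did. Of the 10 splits of the 6 arrays in each, 5, 2, 8 and 4 gave as many lists with the preset correlation. Every other split keeps most transduced arrays on the same side, so part of the real effect remains. These counts therefore do not measure how often lists are called by chance. Statements on lists rest on member counts and the estimated correlation.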

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

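In this part, the tests of the array that stood apart, of the differentiation medium, of the level in batch 1 controls and of infection were chosen after the result was seen. The other tests were set down before it. Bootstrap intervals in this part resample the genes of a list and not the arrays. They treat genes as independent and leave out the spread between arrays.

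The response to MyoD differed between MEFs and P19 cells by a limma test of the difference itself in 3840 genes. The rises larger in MEFs were led by Tnnt3 (8.31), Mymk (8.00), Acta1 (7.72), Tmem182 (7.55) and Mymx (7.53, all log2), genes of contraction and myoblast fusion or of muscle. The effects lower in MEFs were led by Cxcl5 (-5.88), Lcn2 (-5.37), Col11a1 (-4.89), Saa3 (-4.75, with effects of -3.62 in MEFs and 1.13 in P19 cells) and Pxylp1 (-4.71, with -3.03 and 1.68). Of 100 regroupings of the arrays within each cell type, 1, the real one, gave as many genes, and the highest of the others gave 3721. Regroupings that kept the MEF groups and mixed only the P19 arrays gave 3153 to 3721, since they keep the MyoD effect in MEFs, and those that mixed both gave 0, since mixed groups widen the spread. The regroupings therefore decide nothing about a difference of effects, here and for the 3 differences that follow, where mixing both gave at most 3 genes.

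The difference from control was not the same in MEFs labelled NeuroD2 as in P19 cells with NeuroD2 in 1849 genes, by the same test. Mest (6.18), Igfbp5 (5.09), Tnr (4.49), Col18a1 (4.39) and Bmp4 (4.30) had the higher effects in MEFs labelled NeuroD2. Mmp3 (-7.92), Ccl11 (-7.46), Chgb (-6.96), Nhlh2 (-6.39) and Neurod1 (-6.18) had the lower ones. Of 100 regroupings 1, the real one, gave as many genes, and the highest other gave 1323.

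P19 cells with MyoD and P19 cells with NeuroD2 differed in their effects in 1006 genes by the test of the difference. These groups come from batches 1 and 3, so factor and batch are not separated. Klhl41 (4.95), Synpo2l (4.86), Myod1 (4.13), Lurap1l (3.46) and Tnnc2 (3.37) had higher effects with MyoD. Synpo2l was -0.19 without probe sets that can match several transcripts. Another of its probe sets outside that class rose by 3.54 with MyoD in P19 cells (limma adjusted p = 3.47e-09). Chgb (-6.77), Nhlh2 (-6.08), Neurod1 (-5.97), Rgs4 (-5.36) and Uncx (-5.23) had higher effects with NeuroD2. The highest of the other regroupings gave 771, and 1 of 100, the real one, gave as many.

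MEFs with MyoD and MEFs labelled NeuroD2 differed in their effects in 3427 genes by the test of the difference. Tnnc2 (8.98), Tnni1 (8.96), Actc1 (8.87), Mylpf (8.69) and Myog (8.68) had higher effects in MEFs with MyoD. Serping1 (-5.66, with effects of -1.60 and 4.06), Fat4 (-5.62, with -3.68 and 1.94), Dner (-5.31), Plscr2 (-5.03, with -3.51 and 1.52) and Slc35f1 (-4.81) had higher effects in MEFs labelled NeuroD2. Here 1 of 100 regroupings, the real one, gave as many, and the highest other gave 2198. These groups come from different batches, and only the MEFs with MyoD are stated to be in differentiation medium. Factor, medium and batch are therefore not separated.

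The probe set for 18S ribosomal RNA, used in no comparison, read 12.88 in P19 NeuroD2 replicate 1 of batch 3. The other NeuroD2 arrays of that batch read 8.52 and 7.0, its controls 6.10, 11.9 and 6.23, and the arrays of the other batches 7.63 to 8.08.

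Sarcomere genes rose more with MyoD in MEFs than in P19 cells. Without P19 control replicate 2 of batch 1 the median difference was 4.46 (95% bootstrap interval 2.57 to 5.34), which argues against that array as the source. If fewer P19 cells carried MyoD and each responded as MEFs did, sarcomere genes would rise on the linear scale by the same share of the MEF rise as Myod1, which was 11.4% (9.66% to 12.8% over pairs of arrays). The median share over the 36 sarcomere genes that rose in MEFs was 0.690% (0.116% to 1.11%), with 5 genes above Myod1. Without the array it was 1.05% (0.564% to 2.54%). If array signal is proportional to RNA, this argues against a smaller share of cells alone. A lower level of MyoD in each P19 cell may contribute and stays open. So do the state of the cell type, the differentiation medium and the harvest time, since 0 arrays part medium from cell type.

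Interferon genes fell with MyoD in MEFs, which were compared with untransduced cells. Against the MEF controls of batch 2 the median over the list was -1.60 (95% bootstrap interval -2.29 to -0.75), with 21 genes lower and adjusted p = 0.000459 with an estimated correlation. This interval reaches past -1, the bound set for the test, so a high level in the batch 1 controls could account for part of the fall. The MyoD effect less the effect in MEFs labelled NeuroD2 had a median of -1.96 (-2.74 to -0.95, camera adjusted p = 0.000179 with an estimated correlation). The list thus fell further with MyoD than in the other MEFs given virus. Those MEFs are from another batch, are not stated to be in differentiation medium and have no stated harvest time. The contrast therefore cannot decide on infection. The interval of the contrast also reaches past that bound, and infection is not excluded. For the medium, 0 control arrays were stated to be in it, and an effect of MyoD itself and the medium cannot be told apart.

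Neuronal lists rose with NeuroD2 in P19 cells and were not called in MEFs labelled NeuroD2, where 6 of 34 neuronal cytoskeleton genes, 1 of 35 neuronal transcription factors, Dner and Tnr rose, and no rise of Neurod2 RNA passed the test. If these MEFs held no NeuroD2 activity and responded only to infection, genes raised by NeuroD2 in P19 cells and not called higher with MyoD would overlap those raised in the MEFs by chance alone. Of 16029 genes not called higher with MyoD, 372 and 295 rose at least 2-fold, and 36 were shared where 6.85 were expected (Fisher's exact p = 2.88e-16, odds ratio 6.37). This does not exclude infection alone, because a gene not called with MyoD can still respond to infection (the simulated tests of MyoD in P19 cells and MEFs recovered 79.1% and 82.1% of 2-fold changes), so the bound set for this test was wrong. With the controls of the other batch on both sides the median difference over the neuronal cytoskeleton list was -1.80 (95% bootstrap interval -2.57 to -0.67). It was -1.34 without the array that stood apart. The median thus stayed negative, but camera gave adjusted p = 0.183 with an estimated correlation, against 0.0263 with their own controls. The state of the controls is therefore not excluded. An absence or lower level of NeuroD2 in the MEFs, their cell state and the batch may each contribute and stay open.

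For the main comparisons, the 6 arrays of each make 10 splits, which are too few for a share under 0.05, and 1 of the 10 gave as many genes in each. The real and highest other counts were 493 and 0 (MyoD in P19 cells), 4601 and 0 (MyoD in MEFs), 1517 and 108 (NeuroD2 in P19 cells), 2246 and 0 (MEFs labelled NeuroD2), 9398 and 1587 (MEF against P19 controls), 2569 and 1197 (P19 controls between batches), and 415 and 0 (MEF controls between batches). For gene lists, 5, 2, 8 and 4 of the 10 splits gave as many as the real 13, 13, 12 and 4, and the highest others gave 15, 13, 15 and 7. The other splits keep most transduced arrays on the same side and so part of the real effect, so they give no rate of chance calls of lists. For overlaps of risen genes, 1 of 100 regroupings, the real one, gave as many as 84 (MyoD in both cells), 68 (P19 cells with NeuroD2 and MEFs labelled NeuroD2), 42 (both factors in P19 cells) and 115 (MEFs with MyoD and MEFs labelled NeuroD2), with 0 as the highest other of each. In each overlap the other splits of at least 1 comparison called 0 genes 2-fold higher, which fixes the overlap at 0 wherever that comparison was regrouped. Other splits of NeuroD2 in P19 cells called at most 2 such genes, which leaves little to share. The regroupings of overlaps therefore decide nothing.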

How the results depend on the processing

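Leaving P19 control replicate 2 of batch 1 out of every fit was chosen after seeing the data, and the other settings before. Named genes and lists were sorted, in order, into same call status, call lost, call gained and sign changed. Results not called in either fit counted as the same whatever their sign. A changed sign needed a call in only 1 of the fits. The numbers were 307, 34, 0 and 0 at adjusted p under 0.01, and 336, 4, 0 and 1 with arrays shifted to one median. For the lists they were 16, 26, 0 and 0 with an estimated correlation, and 33, 9, 0 and 0 with fry. The other batch's controls gave 233, 22, 8 and 8, and leaving out dim genes gave 315, 5, 0 and 0. A trended robust prior gave 339, 2, 0 and 0, and each array left out in turn gave 2182, 100, 2 and 2. The mean of all probe sets gave 333, 7, 1 and 0, and only the arrays compared gave 296, 43, 2 and 0. Without that array they were 324, 12, 4 and 1, and with quantile normalization again 329, 9, 2 and 1. Without probe sets that can match several transcripts they were 326, 8, 0 and 3. The pseudocount alternative was not run, because the values are already log2. Low signals near background limit what can be seen of weakly expressed genes. The cause of a change was not tested unless stated.

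Medians of called lists changed sign for G2 and M phase with MyoD in P19 cells (-0.002 with quantile normalization again, -0.001 without that array) and for lineage bHLH factors with NeuroD2 in P19 cells (-0.03 with arrays shifted). Without probe sets that can match several transcripts, another probe set stood in for Igfbp5 (-0.095) and Synpo2l (-0.273) with MyoD in P19 cells, and Synpo2l was -0.191 for MyoD less NeuroD2 in P19 cells. A further Synpo2l probe set outside that class rose by 3.54 with MyoD in P19 cells (limma adjusted p = 3.47e-09). Against the other batch's controls, MyoD in P19 cells gave Ankrd1 0.25, Id1 -0.477, Id3 -0.966, and medians of 0.024 for the endothelial and 0.018 for the blood list. MyoD in MEFs gave Myf5 0.048, and NeuroD2 in P19 cells gave Klf2 0.021 and Oasl2 0.062. Of these, Id1 and Id3 were called in the new direction (limma adjusted p = 0.0142 and 0.000824), and the others were not called.

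Counts are higher then lower genes where 2 are given. In comparisons named NeuroD2, the MEFs are those labelled NeuroD2. Without that array, limma called 337 lower (MyoD in P19 cells), 3302 and 4087 (MyoD in MEFs), 1992 and 2034 (NeuroD2 in P19 cells), and 2506 and 2422 (MEFs labelled NeuroD2). It called 4520 for NeuroD2 in MEFs less P19 cells, 1996 and 6498 for MyoD less NeuroD2 in P19 cells and MEFs, and 2970 between MEF batches, and 27 genes rose with both factors in P19 cells. The array carries much of the spread that limma pools over groups. With only the arrays compared the counts were 45 and 5 (MyoD in P19 cells), 4229 and 4890 (MyoD in MEFs), 2760 and 2535 (MEFs labelled NeuroD2), 2658 and 2417 (MEF against P19 controls), 2536 (MyoD, MEFs less P19 cells), 3026 (NeuroD2, MEFs less P19 cells), 321 and 7871 (MyoD less NeuroD2 in P19 cells and MEFs), 1 and 3154 (P19 and MEF batches), overlaps of 33 (MyoD in both cells) and 8 (both factors in P19 cells), and 2 lists in MEFs labelled NeuroD2.

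At adjusted p under 0.01, a stricter threshold, the counts were 196 and 33 (MyoD in P19 cells), 245 lower (NeuroD2 in P19 cells), 2427 and 1225 (MEFs less P19 cells for MyoD and NeuroD2), 537 (MyoD less NeuroD2 in P19 cells), 914 and 182 (P19 and MEF batches), and 2 lists in MEFs labelled NeuroD2. With a 2-fold minimum, which only removes genes, they were 181 and 27, 823 and 1081, 481 and 113, and 463 and 433 for MyoD in P19 cells and MEFs and NeuroD2 in P19 cells and MEFs, and 2655 and 1978 for MEF against P19 controls. Without that array the 2-fold counts were 118 and 45 for MyoD in P19 cells and 2040 and 2437 for MEF against P19 controls, where the balance turned. With all arrays the 2-fold counts were 2259 and 1175 for MEFs less P19 cells (MyoD, NeuroD2) and 648 and 2028 for MyoD less NeuroD2 (P19 cells, MEFs). They were 415 and 113 for P19 and MEF batches (106 higher and 103 lower between P19 batches without that array). Without a fold minimum the overlaps of higher genes were 169 (MyoD in both cells), 176 (P19 cells with NeuroD2 and MEFs labelled NeuroD2), 89 (both factors in P19 cells) and 305 (both in MEFs). With an estimated correlation 2 and 6 lists passed for MyoD in P19 cells and MEFs and 0 in MEFs labelled NeuroD2.

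Quantile normalization again gave 348 lower (MyoD in P19 cells), 1083 lower (NeuroD2 in P19 cells), 1700 lower (MEFs labelled NeuroD2), 2824 (NeuroD2, MEFs less P19 cells) and 1211 (MEF batches). Against the other batch's controls there were 934 and 1142 genes for MyoD and 3046 and 2077 for NeuroD2 in P19 cells.

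Leaving out each array in turn gave 202 to 4837 higher and 36 to 3027 lower for MyoD in P19 cells, 330 to 704 lower for NeuroD2 in P19 cells, 3147 to 6069 for MyoD in MEFs less P19 cells, 719 to 2470 for MyoD less NeuroD2 in P19 cells, 1576 to 7607 between P19 batches and 186 to 270 between MEF batches. Overlaps were 61 to 147 (MyoD in both cells) and 27 to 78 (both factors in P19 cells), and 2 to 4 lists passed in MEFs labelled NeuroD2. The median of G2 and M phase with MyoD in P19 cells was -0.001 to 0.424, and that of lineage bHLH factors with NeuroD2 in P19 cells -0.002 to 0.153.

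Whether replicate numbers pair the samples stays open. Same-numbered samples had correlations of deviations from -0.194 to 0.342 (MyoD in P19 cells), 0.006 to 0.076 (MyoD in MEFs), 0.049 to 0.170 (NeuroD2 in P19 cells) and 0.041 to 0.155 (MEFs labelled NeuroD2). In the same order, samples with different numbers had -0.337 to 0.313, -0.089 to 0.047, -0.171 to 0.118 and -0.152 to 0.117. The ranges overlap, but outside MyoD in P19 cells every same-numbered value was positive. A fit with the replicate number as a block within each cell type and batch moved no count by over 1.5 times (336 and 83 for MyoD in P19 cells, 2368 and 316 between P19 and MEF batches). In that fit 333 named genes and lists had the same call status, 8 lost a call, 0 gained a call and 0 changed sign.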

Other observations

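In this part, the tests of genes higher in all 4 main comparisons and of imprinted genes were chosen after the result was seen.

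At least 2-fold, 10 genes were higher than in controls in all 4 main comparisons, that is P19 cells and MEFs with MyoD, P19 cells with NeuroD2, and MEFs labelled NeuroD2, where no rise of Neurod2 RNA passed the test. By chance, 0.00551 genes were expected if the comparisons were independent, and 6 of the 10 were higher without P19 control replicate 2 of batch 1 (Dll1, Hes6, Igdcc4, Igfbp5, Megf10 and Plxna2). Dll1, a Notch ligand, was higher by 1.84 and 4.27 with MyoD in P19 cells and MEFs, and by 2.26 in P19 cells with NeuroD2 and 2.25 in MEFs labelled NeuroD2. In the same order, Hes6, a bHLH factor that opposes Hes1, was higher by 1.47, 3.20, 1.36 and 1.05, and Megf10, an engulfment receptor also found in muscle stem cells, by 3.02, 4.26, 2.38 and 3.70. Plxna2, a semaphorin receptor, was higher by 1.65, 1.94, 1.77 and 1.90, and Igdcc4 by 1.90, 2.55, 1.06 and 3.42. Cacna2d1, a calcium channel subunit, Id2, a bHLH inhibitor, Tnik, a kinase, and Zbtb18, a zinc finger repressor, completed the set, with rises between 1.08 and 3.32. Igfbp5 was higher by 4.22, 7.46, 2.83 and 7.92, and another of its probe sets differed by -0.10 with MyoD in P19 cells, where it was not called. All transduced and no control cells received virus, so infection is not parted from the factors in these 10 genes.

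Mest, an imprinted gene, rose in MEFs with MyoD and in MEFs labelled NeuroD2, and a hypothesis was that imprinted genes rise together there. A list of 18 other imprinted genes on the array had 3 higher and 5 lower with MyoD (median -0.04; camera p = 0.747 with an estimated correlation) and 2 higher and 1 lower in MEFs labelled NeuroD2 (median 0.02; p = 0.637 with an estimated correlation). Neither test bore it out.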
